A study of Mus musculus with 16 samples.

How the data were processed

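The labels describe polyadenylated RNA sequenced from sorted splenic regulatory T cells of sex- and age-matched mice, stimulated with 1 µg/ml of plate-bound antibody to CD3. Per the submitters' processing notes, STAR 2.6.0a, HTSeq and DESeq2 were used with the mouse build GRCm38.p6, and versions of the latter tools and the counting settings, strand included, are not given in the sources used here. Each library came as a table of 27803 rows with an identifier and a value. The deposited column is headed as a count, but its values are a normalised signal: whole read counts divided by 1 factor per library, as tested on the files. Dividing each library by the value of 1 read (0.432 to 2.18) gave whole reads for 100% of non-zero values within 0.01 reads, with a largest deviation of 2.796e-05. No source states how the factor was computed, and the deposited totals were 4330895 to 4582858. A duplicated row with identical values was removed, which left 27802 features, of which 7188 were at 0 in every library. Within each pair, libraries differed by more than sampling noise, with chi-square over degrees of freedom of 5.26 to 17.3, which does not show that they came from separate mice or separate RNA.

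Of the listed identifiers, 27789 had a symbol in the mouse gene table, but the values under well-known genes showed that the pairing of identifier and value cannot be used. The files therefore do not pair features with genes in a usable way, and no feature was renamed from its place in the table. The 31 gene lists fixed before the data were examined were tested only as listed, with camera. None of the 155 tests of genotype differences, 93 of interactions and 186 of changes over time passed, with a lowest adjusted p of 0.5468 at a correlation of 0.01 and 0.9803 with an estimated correlation. These tests say nothing about the lists, because their members are not identified. The planned test of features near Sh2d2a and the planned list alternatives were left out for that reason.

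The tests chosen before the data were examined assumed raw counts. Since the files hold normalised values, the main test was limma 3.58.1 in R 4.3.3 with a trended, robust prior variance on log2(value + 2), over the 12391 features with a value of at least 10 in at least 2 libraries, which hold 99.8% of the reads. Fold changes on this scale understate changes of low features. The pseudocount, filter and prior were chosen after the unit was known. One model with a mean for each of the 8 groups left 8 residual degrees of freedom. It gave the genotype difference at each time, their average, joint tests, each time against 0 h within a genotype, and the interactions. P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05, and the error of a log2 change is its moderated standard error. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. edgeR called 18, 31, 75 and 718 features between genotypes at 0, 2, 8 and 24 h, and 18, 26, 72 and 615 of these were also called by limma.

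Reads were simulated with the real features and depths, a spread taken from its trend with abundance, and 200 features changed. Spread particular to single features was left out, so the rates may be too favourable. The test of KO against WT at 24 h (12079 features) recovered 78.8% of 4-fold, 47.8% of 2-fold and 4.5% of 1.5-fold changes, with 11 false among 98 calls. The test of KO at 24 h against 0 h recovered 80.3%, 50.7% and 7.5%, with 10 false among 102 calls. The test of WT at 24 h against 0 h (12100 features) recovered 78.8%, 44.8% and 9%, with 6 false among 94. The averaged comparison (12069 features) recovered 98.5%, 80.6% and 65.7%, with 8 false among 171. The interaction at 24 h (12079 features) recovered 69.7%, 20.9% and 1.5%, with 3 false among 64 calls.

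Features to be printed were to be the 8 largest changes per direction and comparison among those called, with libraries of the groups not overlapping (for the average, one sign at all 4 times) and at least 5 CPM, plus the 10 leading interactions. Because the features have no usable names, at most 2 per direction were printed for the averaged comparison and for WT at 24 h, with the leading pair of interactions and the features called in KO. Alternatives were another scaling, filter, test, set of libraries, pseudocount, depth and block, and leaving out each library. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 served the identifier checks and plots.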

Results

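RNA abundance was measured in regulatory T cells sorted from mouse spleen as CD4-positive cells with high CD25, from C57BL/6 wild-type mice (WT) and from mice with a knockout of Sh2d2a (KO). Sh2d2a encodes TSAd, an adaptor protein that binds the T-cell kinase Lck. The cells were left unstimulated (0 h) or were kept for 2, 8 or 24 h on plates coated with an antibody to CD3, which engages the T-cell receptor complex. Each of the 8 combinations of genotype and time had 2 libraries, 16 in all. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical. Recovered library depth was 2726097 to 10229138 reads in WT and 2065662 to 5907998 reads in KO. In units of M reads, the mean was 6.12 ± 2.57 in WT (SD, n = 8) and 3.66 ± 1.1 in KO (SD, n = 8). A feature without reads could hold up to 3 reads, which is 0.293 CPM in the deepest library and 1.45 CPM in the shallowest, for counting error only.

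The gene identifiers in the deposited tables did not go with the values beside them. The row listed as Sh2d2a had normalised counts of 0 to 4.22 over the 16 libraries, with a median of 0 and WT libraries included, so it checks nothing about the genotype labels. The rows listed as Gapdh, Rplp0 and Ptprc, a glycolytic enzyme, a ribosomal protein and the leukocyte antigen CD45, were at 0 in every library. The row listed as Cd4, the marker by which the cells were sorted, had a mean of 0.08, and the row listed as Foxp3, the lineage factor of regulatory T cells, never exceeded 2.53. Of 30 listed genes that every cell or every T cell uses, 14 had a mean under 10 and 5 were at 0 throughout, and their median percentile among the 27802 features was 61.1. The changes below are therefore changes of measured features whose gene is not identified here. A feature is called by its listed identifier only to mark its row, and no gene list or pathway is read from the identifiers.

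The first question was which features differed between the genotypes, and at which times. Before stimulation 20 of 12391 tested features differed, 6 higher and 14 lower in KO. The number was 26 after 2 h (3 higher, 23 lower), 98 after 8 h (20 higher, 78 lower) and 629 after 24 h (190 higher, 439 lower). Of the 629 features at 24 h, 28 were at least 2-fold higher and 173 at least 2-fold lower in KO. All calls are by limma with Benjamini-Hochberg adjustment at an adjusted p of 0.05. Without the first WT library of 24 h, the deepest of the series, the 24 h count fell to 125, and without the first KO library of 24 h it was 416. The 8 h count ranged from 30 without the first WT library of 8 h to 155 without the second KO library of 8 h, and it was 34 without the second WT library and 52 without the first KO library of that time. The 2 h count was 13 without the first KO library and 43 without the second WT library of 2 h, and the 0 h count was 13 without the first WT library of 0 h. The direction at 0 h rested on single libraries too: 44.4% of 18 features were lower without the first KO library of 0 h, against 70% of the 20.

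Averaged over the 4 times, 830 features differed, 274 higher and 556 lower in KO, with a median absolute change of 0.44 on the log2 scale. With 1 time left out of the average the count was 712 without 0 h, 714 without 2 h, 519 without 8 h and 406 without 24 h, and it was 405 with reads summed over times. Whether differences recurred was read at times left out of the comparison that picked the features, a test chosen after the data were seen. The variance of each feature still came from all libraries. Libraries of different times may also share cells, so recurrence in separate material is not shown. Of the features called in the average of 0, 2 and 8 h, 274 were lower and 132 higher in KO. At 24 h 86.9% of those lower and 81.8% of those higher had the same sign, against 52.1% and 47.9% of all tested features. Of the 439 features called lower at 24 h, 90.4% were lower at 8 h, 71.1% at 2 h and 67% at 0 h, with median log2 differences of -0.29, -0.18 and -0.12. Of the 190 called higher at 24 h, 85.8% were higher at 8 h, 63.2% at 2 h and 56.3% at 0 h, with medians of 0.17, 0.07 and 0.03, so they recurred little at 0 h. Of all tested features 48.6% were higher at 8 h, 49.9% at 2 h and 48.8% at 0 h, and 51.4%, 50.1% and 51.2% were lower. In the set of 830, chosen on all 4 times, the lower features had median log2 differences of -0.36 at 0 h, -0.36 at 2 h, -0.47 at 8 h and -0.72 at 24 h, and the higher ones 0.35, 0.28, 0.39 and 0.47. Across features, the genotype differences at one time correlated with those at another with a Pearson r of 0.15 to 0.24. Features are not independent replicates, and no library is shared between times. The averaged count was 541 without the first KO library of 2 h and 548 without the first WT library of 24 h.

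At every time, the feature listed as ENSMUSG00000028837 was lower in KO. Its normalised count was 262 ± 21 in WT and 89.4 ± 3.1 in KO at 0 h (SD, n = 2 each), and 323 ± 10.7 against 86.8 ± 2.7 at 24 h. Its averaged log2 difference was -1.71 ± 0.1 (SE; limma adjusted p = 1.159e-13), and all 8 KO libraries lay below all 8 WT libraries. Because the features are unnamed, it is not known whether this one or another is the transcript of the targeted gene itself. That listed as ENSMUSG00000019872 had an averaged log2 difference of -1.49 ± 0.23 (SE; limma adjusted p = 4.809e-05), with group means of 24 to 59.5 in WT and 9.1 to 14.1 in KO. In the other direction, the feature listed as ENSMUSG00000042073 had 778 ± 161 in WT and 2668 ± 356 in KO at 0 h (SD, n = 2 each). Its averaged difference was 1.81 ± 0.1 (SE; limma adjusted p = 1.252e-07). Also higher was the feature listed as ENSMUSG00000042821, near 9.2 in WT and 45.4 in KO at 0 h with an averaged difference of 2.13 ± 0.24 (SE; limma adjusted p = 1.637e-07). In all, 8 features passed the test at each of the 4 times, 6 lower and 2 higher in KO. A joint test of the 4 times found 541 features that differed at one or more of them, and 269 without the first WT library of 24 h.

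The second question was how each genotype responded to stimulation. No library held cells kept for 2, 8 or 24 h without the antibody. Changes against 0 h may therefore include effects of time in culture. In WT cells the number of called features grew with time: 11 features changed after 2 h (all higher), 68 after 8 h (67 higher, 1 lower) and 692 after 24 h (441 higher, 251 lower). The upward direction at 2 h depended on the second WT library of 0 h, without which 52.9% of 17 features were lower, against 20% of 10 without the first. At 8 h most features were higher without either, with 19.3% of 57 lower without the second and 14% of 50 without the first. With DESeq2 22.6% of 31 and 12.9% of 101 were lower. Of those at 24 h, 157 rose and 20 fell at least 2-fold. Among the largest rises, the feature listed as ENSMUSG00000026805 went from 4 ± 1.3 at 0 h to 103 ± 35.4 at 24 h (SD, n = 2), a log2 change of 4.11 ± 0.6 (SE; limma adjusted p = 2.517e-05). The feature listed as ENSMUSG00000090812 went from 0.8 ± 1.1 to 59.6 ± 8.1 (SD, n = 2), a log2 change of 4.53 ± 0.89 (SE; limma adjusted p = 0.001177) that depends on the pseudocount at so low a start. Its adjusted p was 0.05462 without the first WT library of 24 h. Among the features that met the naming rule, which 249 of the 251 lower ones did, the largest falls were smaller. That listed as ENSMUSG00000027751 went from 107 ± 32.8 to 38 ± 16.5 (SD, n = 2; limma adjusted p = 0.001083), and the feature listed as ENSMUSG00000062691 from 48 ± 14.4 to 15.7 ± 2.1 (SD, n = 2; limma adjusted p = 0.01619). The first fall had an adjusted p of 0.05561 without the first WT library of 0 h and 0.06099 without the second of 24 h (limma). The second had 0.2336 without the second WT library of 0 h and 0.1813 without the first of 24 h, and 0.06151 with reads thinned to one depth (limma). The WT count at 24 h was 161 without the first WT library of 24 h, 405 without the first WT library of 0 h and 392 without the second. The WT count at 8 h was 30 without the first WT library of 8 h and 43 without the second.

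In KO cells few features were called. The test called 1 feature after 2 h, 2 after 8 h and 2 after 24 h. At an unadjusted p under 0.05 (limma) there were 587, 869 and 829 features in KO, where chance alone gives 620. In WT there were 411, 820 and 2170, so by this count KO was not below WT at 2 and 8 h. On the recovered reads edgeR called 1, 0 and 0 in KO, with 590, 695 and 755 at an unadjusted p under 0.05. The calls were few enough to name, and the features below were chosen after their values were seen where the naming rule did not reach them. The feature listed as ENSMUSG00000024112 was called in both genotypes. In KO it went from 133.6 and 136.5 in the libraries of 0 h to 420 and 271.2 at 2 h, a log2 change of 1.31 ± 0.18 (SE; limma adjusted p = 0.0003103), and its changes at 8 and 24 h were 0.96 and 1. Its KO call at 2 h ended without the first KO library of 2 h (limma adjusted p = 0.06118) and with a random replicate block and voom (0.0683). In WT it went from 88 and 106.7 to 767.1 and 666.3, a log2 change of 2.86 ± 0.18 at 2 h (SE; limma adjusted p = 1.495e-12). The feature listed as ENSMUSG00000029723 had a log2 change of 1.31 ± 0.2 in KO at 24 h (SE; limma adjusted p = 0.03174) and of 2.36 in WT. That listed as ENSMUSG00000068663 had 28.7 and 28.1 in the KO libraries of 0 h and 2.2 and 2.9 in those of 8 h, and was at 33.3 and 11.4 at 24 h. Each of the KO calls at 8 and 24 h was lost with edgeR, without the first KO library of 0 h and under other settings. ENSMUSG00000068663 also lost its call without the second KO library of 0 h (limma adjusted p = 0.1219) and without the first of 8 h (0.07529). The changes of ENSMUSG00000024112 at 8 and 24 h lost theirs without either WT library of 2 h or the second KO library of 0 h or of 24 h, and that at 8 h also without the second KO library of 8 h or the first of 24 h, with limma adjusted p of 0.05516 to 0.2386. ENSMUSG00000029723 lost its KO call without either WT library of 2 h or either KO library of 24 h (limma adjusted p of 0.05948 to 0.3105). The counts moved with single libraries too. The 8 h count reached 25 (76% lower) without the second KO library of 8 h, the 24 h count reached 21 (81% lower) without the first KO library of 24 h, and the 2 h count reached 10 (60% lower) without the first KO library of 0 h. That library left out gave 6 at 8 h and 10 at 24 h, the second KO library of 0 h left out gave 5, 5 and 6, and none of the other libraries left out gave over 8.

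**Figure D1:**
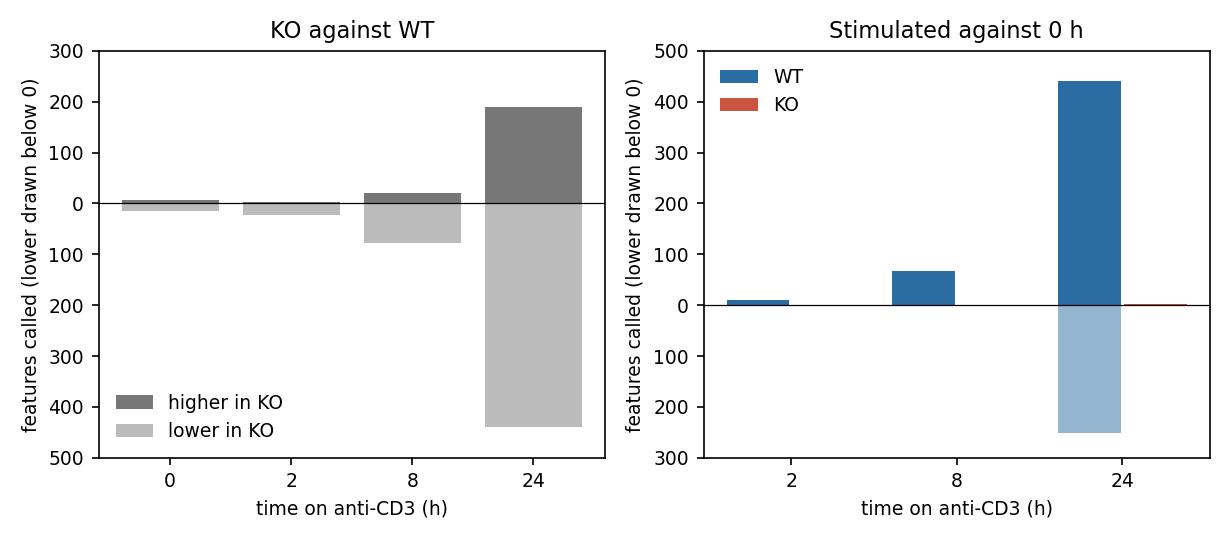
Number of features past an adjusted p of 0.05 (vertical axis; lower features are drawn below 0) by hours on anti-CD3 (horizontal axis, categories). The left panel compares KO with WT, from 20 features at 0 h to 629 at 24 h, and the right panel compares each time with 0 h, where WT reached 692 features at 24 h and KO reached 2.

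The third question was whether the response itself differed between the genotypes, which the interaction of genotype and time tests. It was called for 1 feature at 2 h, for 6 at 8 h and for 93 at 24 h. All 66 features with a negative interaction at 24 h had a WT change above 0, and 65 of them were called as raised in WT. Their median log2 change was 1.26 in WT and 0.02 in KO. All 27 with a positive interaction had a WT change below 0, 26 of them called as lowered, with medians of -0.68 in WT and 0.13 in KO. These features were chosen by the interaction in the same libraries, which by itself moves the WT and KO medians apart. The change was smaller in KO for 65 of the 66 and for 26 of the 27. The joint test over the 3 times called 53 features. In WT the feature listed as ENSMUSG00000029004 rose from 1502 ± 189 at 0 h to 5795 ± 538 at 24 h and was at 1704 ± 124 and 1842 ± 316 in KO (SD, n = 2 each). Its difference of response at 24 h was -1.85 ± 0.16 (SE; limma adjusted p = 1.53e-08). Likewise, that listed as ENSMUSG00000064340 rose in WT from 707 ± 39.3 to 3529 ± 80 and was at 674 ± 73.4 and 784 ± 37.3 in KO (SD, n = 2 each), a difference of response of -2.1 ± 0.21 (SE; limma adjusted p = 1.292e-06). Called at 2 h was the feature listed as ENSMUSG00000024112, at -1.55 (limma adjusted p = 0.009001). This call ended without the first WT library of 0 h (0.07235), the second KO library of 0 h (0.07716) or the second of 2 h (0.08021), by limma, and also with no filter (0.3538) and with a random replicate block and voom (0.1318). That listed as ENSMUSG00000029723 had a difference of response at 24 h of -1.05 ± 0.29, which missed the threshold (limma adjusted p = 0.1141) and passed it without the first KO library of 0 h (0.02922) and with DESeq2 (0.01538). The 24 h count was 24 without the first WT library of 24 h, 168 without the second, 46 without the second KO library of 0 h and 45 without the second KO library of 24 h. The joint count was 19 without the first WT library of 24 h, 23 without the second KO library of 24 h and 93 without the second WT library of 2 h.

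The features that WT cells raised moved less in KO cells. The 441 features called higher in WT at 24 h had a median log2 change of 0.79 in WT and 0.12 in KO, and 302 of them had a change above 0 in KO. The 251 called lower in WT had medians of -0.58 and -0.04. At 8 h the 67 higher features had medians of 0.97 in WT and 0.2 in KO, and at 2 h the 11 higher features had 1.51 and 0.52. These features were chosen in the WT libraries, which raises their WT medians. The comparison was therefore repeated with 200 features of mean normalised count of at least 100, picked as the largest rises in one pair of WT libraries and measured in the other pair. At 24 h the held-out WT pair had a median rise of 0.56 to 0.74 over the 4 ways of picking, and KO had 0.08 to 0.14. The 200 largest falls had held-out WT medians of -0.44 to -0.35 and KO medians of -0.06 to -0.03. At 8 h the held-out WT rise was 0.15 to 0.35 and the KO rise 0.06 to 0.13. At 2 h the held-out WT median was -0.04 to 0.03, so picking by rank did not recover a response that early. Across all tested features the WT and KO changes correlated with a Pearson r of 0.06 at 2 h, 0.05 at 8 h and 0.09 at 24 h. Noise lowers these values. The covariance between separate pairs of KO libraries was below 0 at each time, so this estimate gave no repeatable KO signal over all features. A true signal variance cannot be below 0, so the estimate carries an error, and a KO signal is not excluded. The covariance of the WT with the KO changes was 0.008549 at 2 h, 0.009094 at 8 h and 0.01886 at 24 h. With the WT noise taken out, the slope of KO on WT was 0.21 at 24 h, where the WT signal variance was 0.08902. At 2 h it cannot be read, because the WT signal variance was -0.01638. At 8 h it was 0.41, but the WT signal variance of 0.02244 is near the size of that error, so this slope is uncertain.

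**Figure D2:**
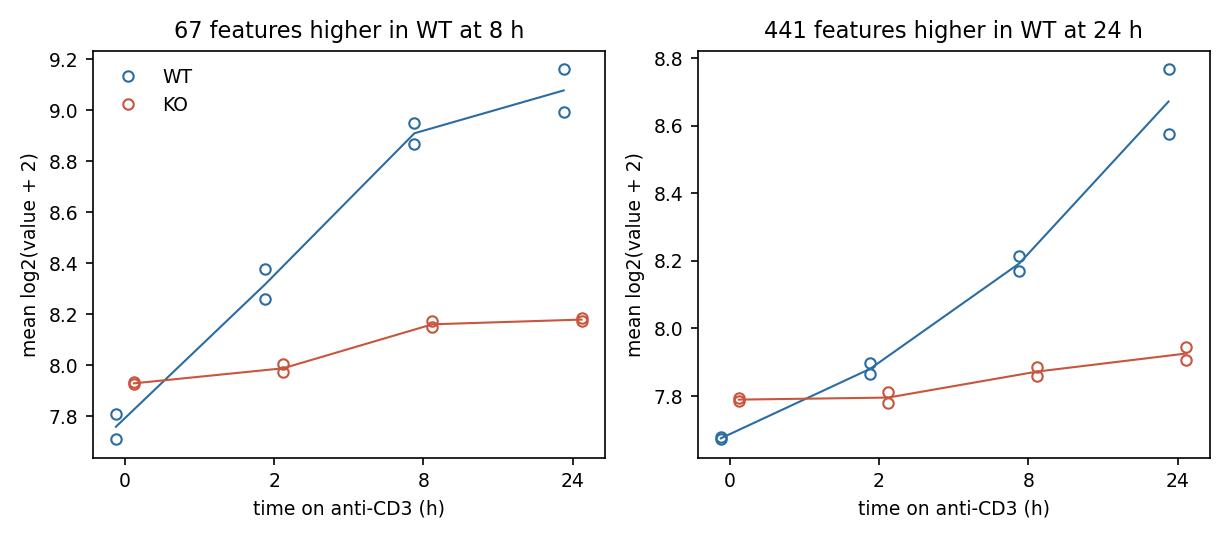
Mean of log2(normalised count + 2) over the features called higher in WT at 8 h (left, 67 features) and at 24 h (right, 441 features), by hours on anti-CD3 (categories). Each circle is 1 library and lines join the group means. The WT libraries of 24 h lie at 8.99 and 9.16 in the left panel, and the KO libraries of 24 h at 8.17 and 8.18. The features were chosen in WT.

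**Figure D3:**
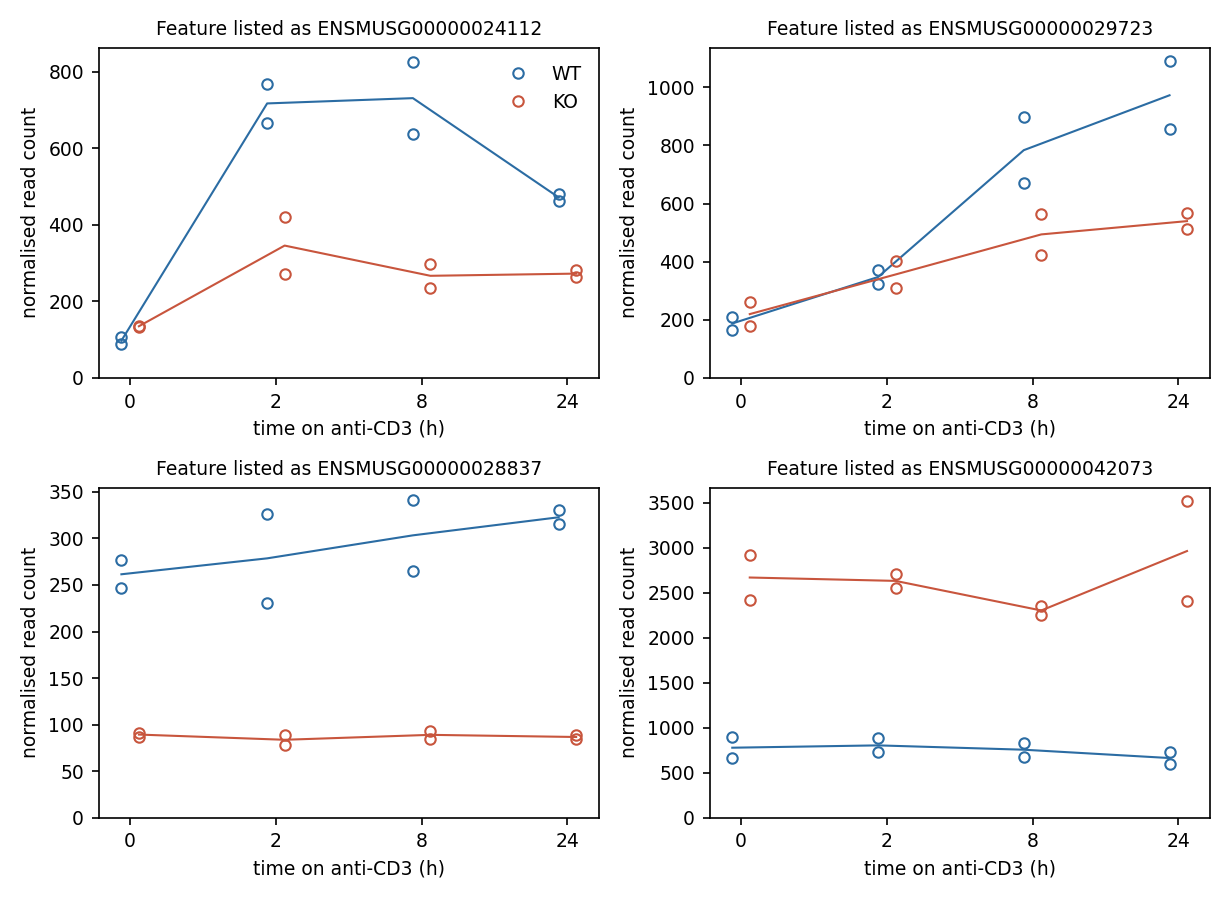
Normalised read count (vertical axes start at 0) of 4 features by hours on anti-CD3 (categories). Each circle is 1 library and lines join the group means. For the upper left feature, listed as ENSMUSG00000024112, the WT libraries of 2 h lie at 767.1 and 666.3 and those of KO at 420 and 271.2. The lower features differed by genotype at every time.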

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

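The tests of depth, of the first WT library of 24 h, of the averages without 1 time and of the identifiers were chosen after the results were seen. The response to stimulation differed between the genotypes by the test of the difference itself, which called 1 feature at 2 h, 6 at 8 h, 93 at 24 h and 53 over the 3 times jointly.

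Far fewer features changed in KO than in WT after 24 h, 2 against 692. With every library thinned to 2065662 reads, WT still had 532 called features and KO 0 by limma (748 at an unadjusted p under 0.05), so the lower depth of KO is not the whole cause. A larger spread between KO libraries is argued against by the features picked in one WT pair, whose median rise in KO was at most 0.14 against at least 0.56 in the held-out WT pair. The median SD on the log2 scale was higher in KO at 24 h, 0.18 against 0.149 in WT, and 0.163 against 0.159 at 0 h. Among 4598 of the more abundant features, pooled over times, it was 0.13 in both genotypes. The main test takes its variance for each feature from all 8 groups together. Its median SE was 0.24 for the change at 24 h in KO and in WT alike. This equality follows from the shared variance and does not measure the KO spread. A larger KO spread would widen the error of KO and WT changes alike in this test. The first WT library of 24 h alone is not the cause, since 161 WT features passed without it, though it carries much of the count. Whether all the KO libraries labelled as stimulated held unstimulated cells was read from the 67 features raised in WT at 8 h. All 6 of these libraries scored above both KO libraries of 0 h, by 0.18 on average (exact permutation p = 0.03571, two-sided, the smallest that 28 regroupings allow). They thus differed from the 0 h libraries. The test cannot decide the question, because no cells were kept in culture without the antibody and time in culture could raise the score too. A weaker response of KO cells remains open as a hypothesis beside a stimulation or preparation that differed with genotype, which the design cannot separate. The scores of the 441 features of 24 h overlapped, with 5 of the 6 stimulated KO libraries above both of 0 h (exact permutation p = 0.1786). The exception was the second KO library of 2 h, at 7.779 against 7.784 and 7.795 at 0 h.

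The genotype difference averaged over times was the second pattern. Of 100 splits of the libraries within times, the real one included, 1 gave as many features as the real 830, and the highest of the others gave 284. For libraries that count as independent this argues against chance, though 100 splits cannot exclude it. The splits with 284 and 263 features kept the real genotypes at 3 of the 4 times, and another split that did so gave 9. Chance differences between a few mice of each genotype are not sampled by these splits and stay open. Thinning to one depth left 632 features, which argues against depth as the whole cause, and leaving 24 h out of the average left 406 and leaving 8 h out 519. A difference of genotype and any difference in breeding or handling that went with it stay open, since no label separates them.

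The listed identifiers went against the values, which was the third pattern. RNA of another cell type or tissue is argued against by 4 of 23 listed genes used by every cell, Gapdh, Rplp0, Ppia and Fth1, that were at 0 in all 16 libraries. An identifier column out of step with the values is a candidate explanation. In the order of listed identifiers, 5 of the 10 most abundant features fell within 37 rows (permutation p = 0.0001, the smallest that 10000 draws can give), which shuffled identifiers would not give but a correct table could, since genes of the mitochondrial genome have adjacent identifiers. The run lay 2244 rows from the nearest of the 31 genes listed as mitochondrially encoded, none of which was among the 10. Their mean values had a median of 0.63, and the highest was 1232.2. No explanation from genotype or stimulation was tested. The values, the libraries and the comparisons do not depend on the identifiers.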

How the results depend on the processing

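The edgeR, pseudocount, TMM, thinning and left-out-time settings were chosen after seeing the data. Of 191 counts under settings other than leaving out a library, 144 stayed within 1.5 times the main count. Of 262 values of 19 printed changes of 13 features under those settings, 0 reversed, 32 lost their call, among them changes in KO and the interaction at 2 h, and 1 gained one. The causes of the shifts below were not tested, except that no filter tests more features. With no filter, KO against WT gave 12, 14, 49 and 353 features at 0, 2, 8 and 24 h, 520 averaged, 261 jointly and 18 joint interactions (36 at 24 h). WT gave 7 at 2 h and 443 at 24 h, and KO 0 at 8 and 24 h. With DESeq2, KO against WT gave 42 at 0 h and 47 at 2 h, WT 31 at 2 h, KO 6, 5 and 9, and interactions 196 at 24 h and 130 jointly. With only the compared groups, KO against WT gave 63 at 2 h and KO 7 at 2 h and 5 at 24 h. Thinning gave 65 for KO against WT at 8 h, 5 for WT at 2 h and 2, 2 and 0 for KO. The averaged count was 405 with reads summed over times, 406 without 24 h and 519 without 8 h. In the averaged comparison 67% of called features were lower in KO in the main test. This share was 55.8% with a random replicate block and voom, 60.5% with DESeq2, 61.3% with TMM and 74.8% with library size only. At 24 h it was 69.8% in the main test, 61% with that block, 63% with DESeq2 and 71.4% with no filter. edgeR with TMM or with RLE gave 0 for KO at 8 and 24 h. For KO at 8 h the pseudocount 0.5 gave 6 and 8 gave 0.

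Over 28 pairs of groups the correlation of deviations by replicate number was -0.08 to 0.17. It was above 0.1 in 2, both within WT: 0.17 for 2 h with 8 h and 0.16 for 0 h with 24 h. Every pair of groups within a genotype was above 0, and pairs across genotypes lay on both sides of 0. The replicate numbers thus showed no clear pairing, but a weak one within WT is not excluded. The replicate block left KO with 1 feature at 8 h and 0 at 24 h, the replicate block within genotype with 3, 1 and 0, and moved no other count by over 1.5 times. A random replicate block with voom gave 51 for KO against WT at 8 h, 1266 for WT at 24 h, 0 for KO at each time and 145 interactions at 24 h.

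Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave ranges of 13 to 28, 13 to 43, 30 to 155 and 125 to 674 for KO against WT at 0, 2, 8 and 24 h. The averaged count ranged from 541 to 843, the joint count from 269 to 662, joint interactions from 19 to 93 and 24 h interactions from 24 to 168. WT ranged from 10 to 17, 30 to 72 and 161 to 767, and KO from 1 to 10, 1 to 25 and 0 to 21. Of 304 values of the printed changes 0 reversed, 29 lost their call and 1 gained one. At these depths changes of 1.5-fold at a single time were mostly not detectable.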

Other observations

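The tests in this part were chosen after the results were seen. Of the 8 features that differed by genotype at all 4 times, 4 lay within 200 rows of each other when the 12391 tested features were put in the order of their listed identifiers, against a median of 2 in random draws of 8 features (permutation p = 0.0011 over 10000 draws). These 4 did not share a direction. That listed as ENSMUSG00000028433 was higher in KO, and those listed as ENSMUSG00000028647, ENSMUSG00000028826 and ENSMUSG00000028837 were lower. Neighbouring features that share a genotype difference may account for the run, as when a stretch of chromosome travels with a knockout allele. With identifiers that do not go with the values, however, the position of these features is not known. The wider sets gave less. Of the 67 features with an averaged difference of at least 2-fold, at most 5 lay in such a run (permutation p = 0.6472), and of all 830 called features at most 30 did, against a median of 25 (permutation p = 0.0162).

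The 10 most abundant features took 7.9% to 9.6% of the reads in WT libraries and 8.9% to 11.9% in KO libraries. On a principal component analysis the first component held 14.5% of the variance and had the WT libraries of 24 h at -40.7 and -27.4. The KO libraries of 24 h lay at 11.9 and 6.1, beside those of KO at 0 h at 17.8 and 14.5. The first KO library of 8 h, the shallowest of the series, stood apart on the second component at -44.7.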
